A study of Mus musculus with 2 samples.

How the data were processed

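Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map cJUN, a DNA-binding subunit of the AP-1 transcription factor, in the embryonic mouse intestine. Per the labels' protocols, whole intestines came from 1 litter of 8 wild-type C57BL/6 embryos at E14.5 and were kept for 24 h in transwell culture. The tissue was dissociated and crosslinked, and its chromatin was sheared to about 500 bp. A rabbit polyclonal antibody pulled down cJUN, and sheared DNA that had not been through the antibody step served as input. There were 2 libraries, 1 immunoprecipitate and 1 input, with 1 library per group, so no value has a replicate error.

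Bowtie 1.1.0 and MACS 1.4 and the mouse build mm9 are named in the submitters' processing notes. Read filters, the treatment of duplicate reads and of reads that align to several places, the peak threshold, and the tool that paired peaks with genes were not given in the sources used here. The handling of duplicate and multiply aligned reads can change how many peaks fall in repeated sequence and how strong they look. The deposited table holds 1 line per peak with its position, length, summit, fold and score, and its 2 nearest genes with signed distances, per the file headers. In it 2057 peaks listed 2 genes, 577 listed 1, 106 listed none and 1 listed 3. The fold is a ratio of the immunoprecipitate over the background, as the authors' caller gave it, per the file headers. The score is 10 times the −log10 of the authors' p-value for the peak, per the file headers, so a score of 100 stands for a −log10 p of 10. Positions, lengths and distances are deposited in bp. Fold and score are the authors' values throughout and were used only to describe, rank and filter peaks within this list. Total reads of the libraries were not used here, so their depth is unknown.

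Coordinates are printed as deposited, on mm9. Whether starts count from 0 or 1 is not stated in the file. The end minus the start equals the length for all but 1 peak. The sign of a distance is not defined in the file, so absolute distances are given. Of 936 genes listed at 2 or more peaks, 926 (98.9%) had distances that placed the gene at 1 position to within 1 bp when measured from the peak midpoint, and that position was taken as the start site. Positions relative to exons, introns and untranslated regions were not analysed here, because the annotation used was of another build. Gene symbols were matched to a RefSeq gene table of the assembly GRCm38.p6, which served only for names, biotypes and the order of neighbouring genes. Of 2963 different names, 2870 (96.9%) matched by symbol or by a synonym of a single gene. Of 4535 matched listings, 9 named a gene that the table has on another chromosome.

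The share of peaks within 1 kb of a listed gene's start site was given with an exact Clopper-Pearson 95% interval. All such intervals cover counting error only. Gene list overlap was tested on genes, not peaks. In each of 20 lists fixed before the data were examined, the protein-coding genes listed at any peak were compared with all other protein-coding genes (21900 in the table) by a two-sided Fisher's exact test, with Benjamini-Hochberg adjustment over the 20 lists and a threshold of 0.05. Lists overlap in some members, and 1 peak can count for 2 neighbouring genes. Score ranks were compared in the 10 lists with at least 5 genes at a peak by a two-sided permutation test of the median percentile (100000 permutations), using the highest-scoring peak of each gene. Score and distance were compared across peaks by Spearman correlation with a permutation p. Peaks and genes of 1 library are not independent replicates, so these tests describe this peak list.

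The genes named in the text were set by a rule fixed before the data were examined. It took the 15 peaks with the highest score, with ties broken by fold. It added the 5 peaks with the highest fold, with ties broken by score after the data were seen, up to 3 genes per list by their highest-scoring peak, and every AP-1 subunit gene with a peak. Some genes that this rule takes are not reported here. Genes of clusters, of promoter peaks and of gene families were chosen after their values were seen. The cluster definition, which is 5 or more peaks with gaps of at most 100 kb, was also chosen after the data were seen.

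Alternatives fixed in advance were a score of at least 100, a fold of at least 10, counting peaks within 1 kb once, start site windows of 500 bp and 5 kb, the upper part of peaks by score (at or above the median), all gene symbols as background, the nearest gene only, fold as the score, and peaks within 100 kb. Leaving out clustered peaks and a limit of 50 kb to the listed gene were added after seeing the data. The list test was tested on simulated data with 21900 genes and 20 lists. It recovered a list with a planted 35% added share in 48 of 50 runs and called 1 of 950 unchanged lists. Listed genes were drawn there independently of each other, and the planted list was the Wnt list of 44 genes. Gene spacing, peaks shared by neighbouring genes, and shorter lists were therefore not covered by this check. The fit of read numbers described in the closing section was tested on 1000 simulated peaks, where it recovered 100% of the read numbers and the planted extension length of 70 bp. After shuffling the simulated scores the best length accounted for 35.8%. Computations used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.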

Results

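The genomic sites occupied by cJUN in the developing mouse intestine were examined in 1 cJUN immunoprecipitate and 1 input library, prepared from cultured whole intestines of mouse embryos at E14.5. The whole organ was used, so the chromatin came from a mixture of its cell types. The data are a single list of 2741 cJUN peaks that the authors' caller obtained from the immunoprecipitate against the input. There are no replicate libraries, and no untreated or mutant sample was compared.

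The 2741 peaks were mostly short and near the lower end of the score range. The median fold over background was 16.75, with quartiles of 14.07 and 18.42 and a range from 2.40 to 45.25. The median score, 10 times the −log10 p of the authors' caller, was 61.3, with quartiles of 57.34 and 68.19. The lowest score was 50.01, and 1205 peaks (44.0%) scored below 60. A score of at least 100 was reached by 127 peaks and a score of at least 150 by 43. The median length was 149 bp, and 2662 peaks (97.1%) were shorter than 500 bp.

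None of the 15 highest-scoring peaks was listed at a gene of the AP-1 subunit or AP-1 target lists, and several were listed at predicted genes. Those lists hold 19 and 32 of 21900 protein-coding genes, so their absence from so few peaks says little. The peak with the highest listed score, at chromosome 9 from 3027377 to 3038415 (mm9), was 11038 bp long, with a score of 3189.25 and a fold of 6.12, and lay 9.35 kb from the predicted gene Gm10718. A neighbouring peak at chromosome 9 from 3019522 to 3027346, 113 bp from the start of Gm10718 and 7.78 kb from that of Gm10720, scored 3100. A peak at chromosome 2 from 98506392 to 98507492 had the same score of exactly 3100. Whether 3100 is a measured value or a limit of the caller is not known, so the order of the highest scores is not certain. Of the 15 highest-scoring peaks, 4 lay at Gm10800 and Gm10801 on chromosome 2 between 98502384 and 98507492, with scores of 771.06 to 3100. The next peak, at chromosome 9 from 35112795 to 35113178, scored 1638.31 with a fold of 4.27. It lay 116 kb from Cdon, which encodes a Hedgehog co-receptor, and 37.5 kb from Rpusd4, an RNA pseudouridine synthase gene. A pair of peaks between 7229298 and 7235308 on chromosome 10, listed at Lrp11 and 9230019H11Rik, scored 592.5 and 1433.76. Another pair between 13743482 and 13746064 on chromosome 17 scored 729.68 and 1303.37, and lay about 30 kb from Smok4a and over 150 kb from Mllt4, the gene of the junction protein afadin. A peak at chromosome 4 from 118219804 to 118221346, 4.24 kb from Tmem125 and 72.8 kb from Wdr65, scored 1241.44. The others of the 15 were listed at Rab10, a small GTPase gene, at 922.22, at Gm7148 at 748.7, and at Gm15319 and Gm6483 at 609.47.

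The highest folds were found at other peaks. A peak of 201 bp at chromosome 2 from 10618201 to 10618402 had the highest fold of the list, 45.25, with a score of 163.92. It lay 324 kb from Sfmbt2, a Polycomb-group gene, and 476 kb from Prkcq, a protein kinase C gene. The next 4 had folds of 29.48 to 29.97 and scores of 89.6 to 100.23, where 10 peaks shared the fold of 29.48 and the 3 with the highest scores were taken. These were listed at Rnf182 and Cd83, at Hpgds and C130060K24Rik, at Gm10309 and Prkce, and at Gm14147 and 4921509C19Rik. Across peaks, fold and score had a Spearman correlation of 0.228 (permutation p = 1e-05, the smallest the permutations can give). The 43 peaks with a score of at least 150 had a median fold of 6.12, against 16.75 for the others, and 37 of the 43 had a fold under 10.

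**Figure D1:**
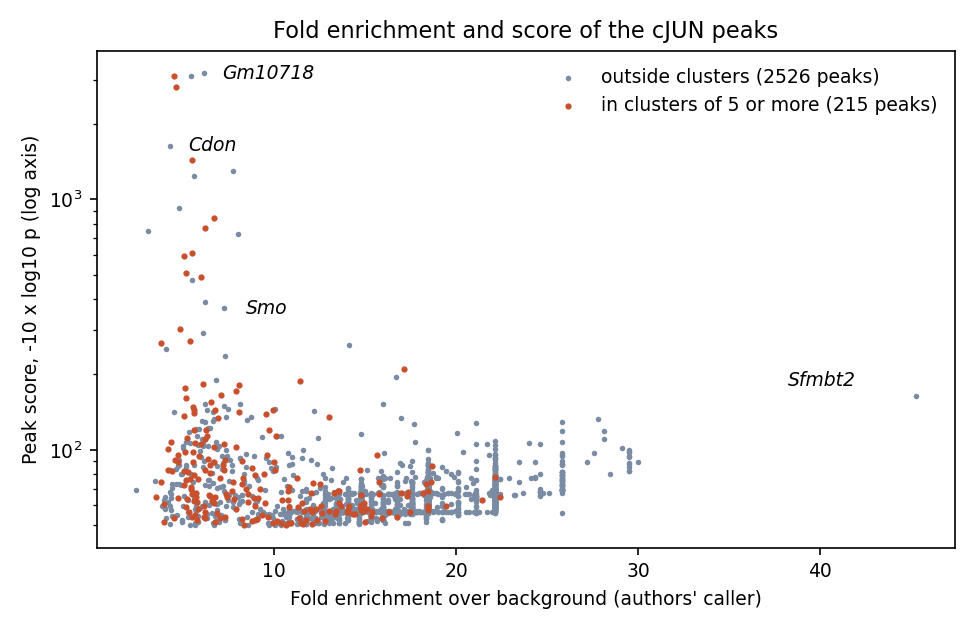
Fold enrichment (x axis, ratio over background) against score (y axis, log axis, 10 times the −log10 p) of the 2741 cJUN peaks, each point a peak, with the 215 peaks in clusters of 5 or more in red. Most peaks lie below a score of 100, and the highest scores stand at folds under 10.

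Peaks were grouped along the chromosomes, as seen after the data were examined. There were 22 clusters of 5 or more peaks, and they held 215 peaks (7.84%). The largest, of 56 peaks, spanned 125.59 kb between Ezh2, the histone H3 lysine methyltransferase gene of the Polycomb repressive complex, and Pdia4, a protein disulfide isomerase gene, at chromosome 6 from 47601605 to 47727195. Its median fold was 5.715 and its median score 82.91. The next clusters held 22 peaks at the imprinted genes Snrpn and Ube3a, at chromosome 7 from 66930199 to 67054876, and 15 peaks at Rhou and Gas8 on chromosome 8. Another 15 peaks lay at 4933400A11Rik and 11 at Srsx and Vmn2r121, both on chromosome X. Clustered peaks had a median fold of 8.47, against 17.59 for the rest. In 1000 uniform placements of the same number of peaks per chromosome, the largest cluster never held more than 8 peaks.

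**Figure D2:**
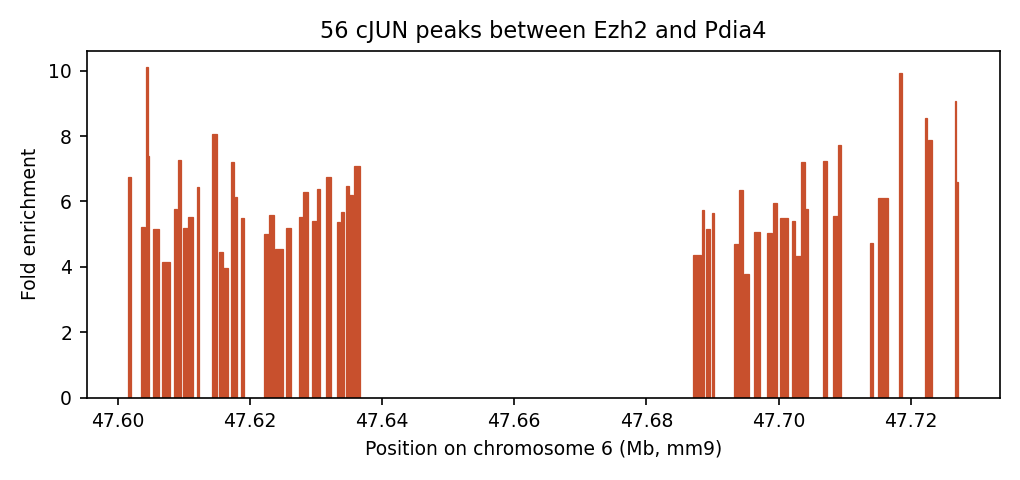
Position on chromosome 6 (x axis, Mb, mm9) and fold enrichment (y axis, starting at 0) of the 56 peaks between Ezh2 and Pdia4, each bar a peak drawn at its position. The peaks form 2 groups with an empty stretch between them, and their median fold is 5.715.

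Few cJUN peaks lay at promoters. Of 2741 peaks, 12 (0.438%, 95% exact interval 0.226 to 0.763) were within 1 kb of the start site of a listed gene, and 74 (2.70%, 2.13 to 3.38) were within 5 kb. The median distance to the nearest listed gene was 89.0 kb, with quartiles of 30.2 and 263 kb, over the 2635 peaks that list a gene. A distance of 5 to 50 kb was found for 844 peaks (30.8%), and 50 to 500 kb for 1445 (52.7%). Another 272 peaks (9.92%) lay more than 500 kb away, and 106 (3.87%) had no gene listed. A comparison of these shares with randomly placed intervals was not analysed here.

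The 12 promoter peaks, taken as a set after their values were seen, included 5 with a symbol of a predicted gene. These were Gm10718 at 113 bp (fold 5.44), Gm10801 at 372 bp (4.58), Gm10800 at 516 bp (4.51), Gm2046 at 754 bp (18.42) and Gm4214 at 945 bp (24.79). The peaks at Gm10718, Gm10801 and Gm10800 are among the 15 highest-scoring peaks. For such high scores, repeated sequence stays a candidate in the closing section. Receptor genes of the vomeronasal and taste systems were represented by Vmn1r158 at 160 bp (fold 10.82) and Tas2r134 at 771 bp (8.23). The remaining peaks lay at Fam214b (278 bp, fold 22.11), Fmo4 (602 bp, a flavin monooxygenase gene, fold 13.16), Rex2 (620 bp, fold 11.58), Lonp2 (732 bp, a peroxisomal protease gene, fold 22.11) and Crebzf (782 bp, a bZIP transcription factor gene, fold 5.89, score 98.95). No member of the 20 fixed gene lists had a peak within 5 kb, among 61 protein-coding genes that did. The highest number expected for any list was 0.142, so this count could not separate the lists. No relation of peak score to distance from the nearest gene was detected (Spearman −0.0144, permutation p = 0.458, across 2635 peaks). The correlation was slight but positive with fold in place of score (0.0478, p = 0.0143).

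**Figure D3:**
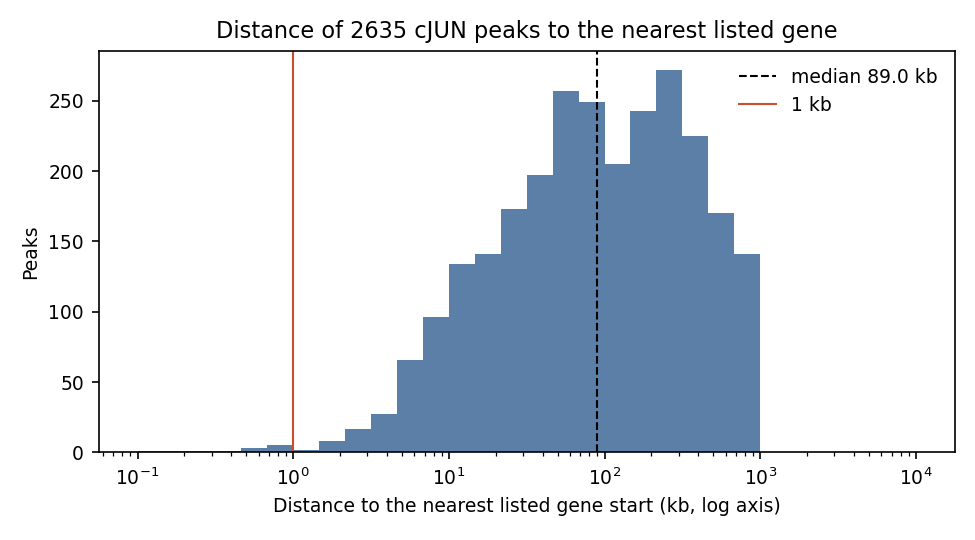
Number of peaks (y axis, starting at 0) by distance to the nearest listed gene start (x axis, kb, log axis) for the 2635 cJUN peaks that list a gene. The dashed line marks the median of 89.0 kb and the red line 1 kb, below which 12 peaks lie.

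Which groups of genes lie beside cJUN peaks was asked with 20 lists. In all, 2745 of 21900 protein-coding genes (12.5%) were listed at a peak. AP-1 genes themselves did not stand out. Among 19 AP-1 subunit genes, 1 had a peak (5.26%, adjusted p = 0.715, Fisher's exact test), and that gene was Atf7. Its peak, at chromosome 15 from 102431060 to 102431200, lay 71.7 kb away with a fold of 15.29 and a score of 64.69. Of 32 known AP-1 targets and feedback genes, 3 had a peak (9.38%, adjusted p = 0.833, Fisher's exact test). They were Vim, which encodes the intermediate filament vimentin, at 90.4 kb with a score of 73.66, Vegfa, a vascular growth factor gene, at 20.3 kb with 66.77, and the growth factor receptor gene Egfr at 89.8 kb with 56.7. Serum-response and immediate-early genes had 7 of 25 (28.0%), which did not pass (unadjusted p = 0.0300, adjusted p = 0.158, Fisher's exact test). Their highest-scoring peaks lay far from the genes, 535 kb from Myc, 903 kb from Klf4 and 241 kb from Ankrd1.

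The enteric neural crest was the list that passed. Of 25 neural crest and enteric neuron markers, 9 were listed at a peak (36.0%, exact interval 18.0 to 57.5), where 3.13 would be expected (odds ratio 3.93, adjusted p = 0.0467, Fisher's exact test). Hand2, a transcription factor gene used in both gut neurons and mesenchyme, had 5 peaks, the strongest at chromosome 8 from 59427520 to 59427699, 372 kb away, with a fold of 18.42 and a score of 72.99. Ret, the receptor gene of the glial-derived growth factor pathway, had 1 peak at chromosome 6 from 118165596 to 118165746, 17.9 kb away, with a fold of 18.42 and a score of 68.9. Further genes of the list with a peak were Elavl4, Elavl2, Stmn2, Gfra1, Chat and Ednrb, named here after their values were seen, and their strongest peaks scored 56.93 to 65.07. The protein-coding genes next to the list's genes were listed in 16 of 49 cases (32.7%), of which 7 rested only on a peak that also lists a gene of the list, so both shares partly count the same peaks. The ratio of listed to expected genes, 2.87, was 3.29 with the upper part of peaks by score and 2.63 with the nearest gene only, and the call ended with both (adjusted p = 0.101 and 0.374, Fisher's exact test). Within 50 kb of the gene, the ratio was 0.897.

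Of the signalling pathways that pattern the gut, 5 lists had shares of 13.04 to 26.5%, against 12.5% for all protein-coding genes, and none passed. The Hedgehog list had 5 of 19 genes at a peak (26.3%, adjusted p = 0.228, Fisher's exact test). Its ratio of listed to expected genes, 2.10, was 3.602 with the upper part of peaks by score (adjusted p = 0.101, Fisher's exact test), 1.38 with the nearest gene only and 1.18 within 50 kb. Besides Cdon, it held Smo, the Hedgehog signal transducer gene, with a peak at chromosome 6 from 29697880 to 29698655, 12.6 kb away, a fold of 7.22 and a score of 367.93. Shh, the ligand gene expressed in gut epithelium, had a peak 412 kb away at chromosome 5 from 29205165 to 29205296, with a fold of 25.79 and a score of 73.82. FGF, EGF and PDGF signalling had 9 of 34 (26.5%, unadjusted p = 0.0317, adjusted p = 0.158, Fisher's exact test), led by Fgf9 at 586 kb, Spry2 at 50.02 kb and Nrg1 at 799 kb. The folds of these leading peaks were 7.37, 16.75 and 18.42. The Wnt list had 10 of 44 (22.7%, adjusted p = 0.209, Fisher's exact test). Its leading peaks were 16.2 kb from Ror2, a Wnt receptor gene, with a score of 150.28, 17.8 kb from Tcf7l1 with 77.33, and 80.04 kb from the Wnt antagonist gene Dkk1 with 75.82. Their folds were 7.24, 25.79 and 22.11. BMP and TGF-beta genes had 7 of 35 (20%, adjusted p = 0.392, Fisher's exact test), with Nog at 221 kb and a score of 128.64, Bmp2 at 958 kb with 75.87 and Inhba at 123 kb with 67. The folds at Nog, Bmp2 and Inhba were 6.19, 21.11 and 22.11. Notch genes had 3 of 23 (13.04%, adjusted p = 1, Fisher's exact test), namely Hey1 at 12.3 kb, Rbpj at 39.0 kb and Nrarp at 19.4 kb. Folds under 10, as at Cdon, Smo, Ror2, Nog and Fgf9, were found at 331 of the 2741 peaks. They include 37 of the 43 peaks with a score of at least 150, for which repeated sequence stays a candidate in the closing section.

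Markers of the other cell types of the whole organ gave no call. Intestinal epithelium markers had 7 of 43 (16.3%, adjusted p = 0.715, Fisher's exact test), among them the splicing regulator gene Esrp1 at 55.4 kb with a score of 81.45, the secretory-lineage gene Atoh1 at 571 kb with 76.86, and Shh. Gut mesenchyme and smooth muscle markers had 5 of 33 (15.2%, adjusted p = 0.770, Fisher's exact test), led by Twist1 at 116 kb with a score of 81.78, then Vim and Hand2. The folds at Twist1, Vim and Hand2 were 5.23, 18.42 and 18.42. Mesothelium markers had 3 of 12 (25%, adjusted p = 0.392, Fisher's exact test), which were Tcf21, Muc16 and Tbx18. Blood and macrophage markers had 4 of 22 (18.2%, adjusted p = 0.578, Fisher's exact test), with scores of 77.86 at Alas2 and 58.17 at Emr1. Endothelial markers had 3 of 22 (13.6%, adjusted p = 0.833, Fisher's exact test), namely Flt1, Cdh5 and Tek. Olfactory and taste receptor genes, which served as a list not tied to the gut, had 2 of 14 (14.3%, adjusted p = 0.814, Fisher's exact test), Olfr15 and Olfr17.

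Matrix, adhesion and growth genes likewise gave no call. Extracellular matrix and basement membrane genes had 10 of 44 (22.7%, adjusted p = 0.209, Fisher's exact test). The highest-scoring of them were the tenascin C gene Tnc at 477 kb with a score of 135.22, the laminin gene Lama1 at 44.2 kb with 89.6, and the thrombospondin gene Thbs1 at 681 kb with 81.6. Their folds were 8.72, 6.61 and 25.79. Integrins, focal adhesion and actin genes had 10 of 51 (19.6%, adjusted p = 0.340, Fisher's exact test), among them Actn1 at 163 kb with a score of 68.19 and Tns1 at 651 kb with 66.8. Cell cycle genes had 3 of 36 (8.33%, adjusted p = 0.770, Fisher's exact test), which were E2f3, Cdkn2c and Ccnb2. Among 28 histone genes, H2afz alone was listed (3.57%, adjusted p = 0.450, Fisher's exact test). None of 36 ribosomal protein and housekeeping genes had a peak (exact interval 0 to 9.74%), where 4.51 would be expected (unadjusted p = 0.0190, adjusted p = 0.158, Fisher's exact test). Of the genes with an Rps symbol other than S6 kinases, a set chosen after its values were seen, 5 of 34 had a peak (14.7%, exact interval 4.95 to 31.1), and of those with an Rpl symbol 0 of 53.

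**Figure D4:**
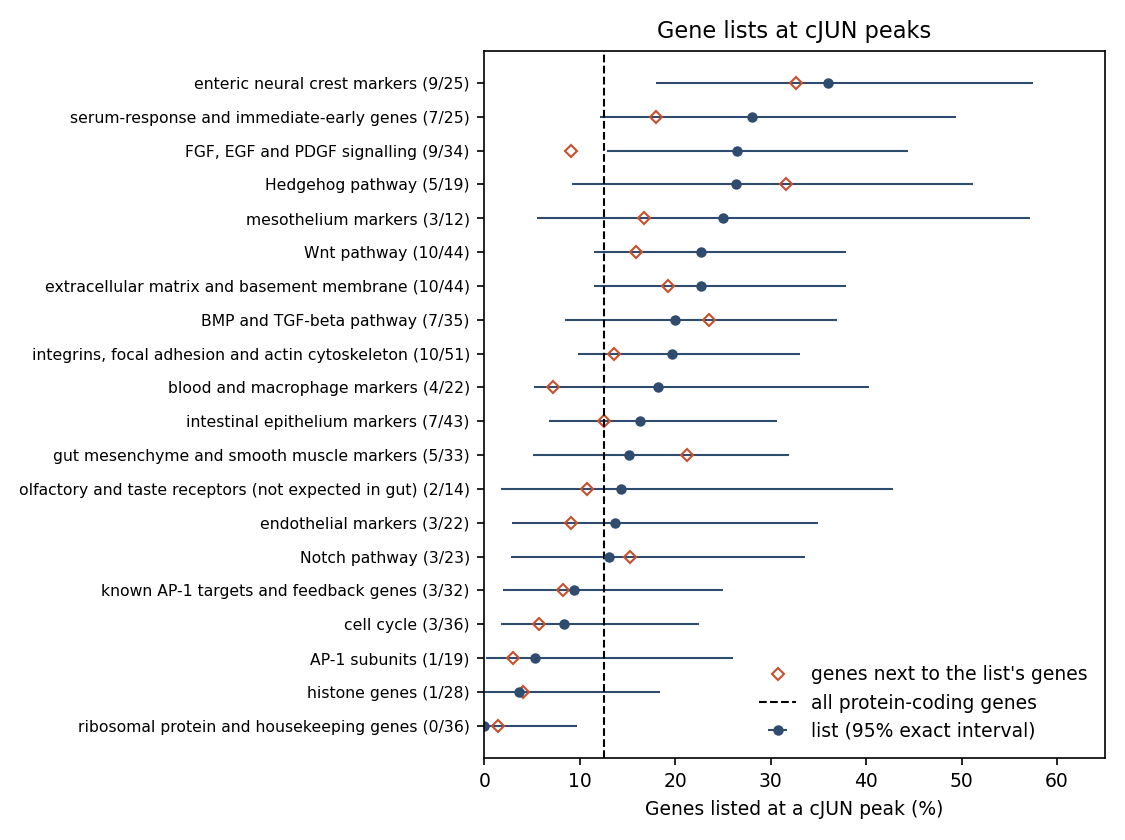
Share of genes listed at a cJUN peak (x axis, %) for each of the 20 lists, with the number listed over the number of genes in brackets. Filled points are the lists with exact 95% intervals, open diamonds the protein-coding genes next to the list's genes, and the dashed line is the share of all protein-coding genes, 12.5%. The enteric neural crest list is highest at 36.0%, with its neighbours at 32.7%, and a peak that lists both genes counts for both.

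In no list were peaks found to be stronger or weaker than at other genes with a peak. The score of each gene's strongest peak was ranked among 2869 genes in 10 lists, and 0 passed, adjusted or unadjusted (permutation test). The median percentile was highest for the Hedgehog list (79.0, adjusted p = 0.375) and the mesenchyme and smooth muscle list (78.1, adjusted p = 0.375, permutation test). It was lowest for FGF, EGF and PDGF signalling (25.01, adjusted p = 0.375) and the Wnt list (28.0, adjusted p = 0.375, permutation test). The enteric neural crest list had a median percentile of 51.8, near that of all genes with a peak (50.2). These lists have 5 to 10 genes each, so a moderate difference in rank could be missed.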

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

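The alternatives that leave out clustered peaks and that limit the distance to 50 kb were chosen after the data were seen. The cause was not tested for any change below except where stated. The number of peaks fell to 127 at a score of at least 100, and stayed within 1.5 times the main count with a fold of at least 10, with peaks within 1 kb counted once, and without clustered peaks. All peaks already lay on numbered chromosomes, X or Y. The share near a start site was 0.146% with a window of 500 bp and 2.70% with 5 kb, which follows from the window. The number of lists that passed, 1 in the main test, was 0 with peaks in the upper part by score, 0 within 5 kb, where no list member was left, 0 with the nearest gene only, 0 within 50 kb and 9 with all gene symbols as background. That background adds noncoding genes and pseudogenes, which the lists do not hold. The neural crest ratio of observed to expected genes stayed above 1 with the upper part by score (3.29, adjusted p = 0.101) and with the nearest gene only (2.63, adjusted p = 0.374, Fisher's exact test), and its adjusted p no longer passed. Of the 19 lists with a listed gene, the ratio moved by over 1.5 times in 6 with the upper part by score, 7 with the nearest gene only, 13 within 50 kb, 19 with all gene symbols as background and 0 without clustered peaks. Other ratios changed side of 1. With the upper part by score they were 0.595 for Notch, 0.622 for endothelial, 0 for mesothelium and 0.978 for olfactory and taste genes. With all symbols they were 1.63 for AP-1 targets and 1.45 for cell cycle. With the nearest gene only they were 1.23 for AP-1 targets, 0.751 for BMP and 0.939 for olfactory and taste genes. Within 50 kb they were 1.18 for AP-1 subunits, 0.897 for immediate-early genes, 0 for BMP, 0.521 for epithelium, 0.679 for mesenchyme, 0.897 for neural crest, 0 for endothelial and 1.25 for cell cycle. With fold as the score, the median percentile of epithelium genes was 38.1. The correlation of score with distance became 0.0478 with fold and 0.0112 within 100 kb. Of the results for single lists, 92 kept their direction and side of the threshold, and 8 passed only with all symbols as background. Of the settings chosen in advance, a limit on the false discovery rate and tag counts as the score were not run, and score ranks within 5 kb gave no value because 0 lists had 5 or more such genes. With 1 library per group and an unknown depth, the lack of a peak does not show a lack of binding.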

Other observations

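Tests of the fold levels, of clusters, of gene families, of chromosomes and of gene spacing were chosen only after the values were seen. The test of the neural crest list without clustered peaks was set before its own result was known, but it could not remove a gene, as described below. Some gene families were listed at cJUN peaks far more often than other genes, by families of shared symbol stem (638 families of at least 5 genes, Fisher's exact test, adjusted over the 638). Cadherin genes had 13 of 23 (56.5%, adjusted p = 0.000131, Fisher's exact test), led by Cdh2, Cdh13 and Cdh18 with scores of 88.7, 75.82 and 74.58. Protocadherin genes outside the tandem clusters had 9 of 12 (75%, adjusted p = 0.000185, Fisher's exact test). The tandem Pcdha, Pcdhb, Pcdhga and Pcdhgb genes together had 3 of 52, all 3 in Pcdhb, a lower share (p = 1.51e-06 for the difference, Fisher's exact test). Tandem genes lie side by side and nearly all peaks list at most 2 genes, so few of them could be listed. The test counts them as independent, so its p may be too small. It cannot separate a family difference from gene spacing. Other families past the threshold were Cntnap with 6 of 7 genes (adjusted p = 0.00308), contactin with 5 of 6 genes and Slitrk with 5 of 6 genes (adjusted p = 0.0132 each, Fisher's exact test). Median distances of their peaks were 657 kb for cadherins, 611 kb for those protocadherins, 604 kb for Cntnap, 224 kb for contactin and 691 kb for Slitrk genes. The genes beside them were listed in 6 of 30 cases for cadherins (p = 0.00924, adjusted p = 0.0739 over 8 families, Fisher's exact test). For the protocadherins outside the tandem clusters, the neighbours were listed in 10 of 19 cases (unadjusted p = 0.274, adjusted p = 0.439, Fisher's exact test). For Cntnap, contactin and Slitrk genes, the neighbours were listed in 7 of 14, 6 of 9 and 5 of 8 cases (unadjusted p = 0.174, 0.604 and 0.580, Fisher's exact test). Neither those protocadherins nor the Cntnap, contactin and Slitrk families were shown to exceed their neighbours. A peak that lists both genes counts for both. Leaving such shared peaks out lowers the neighbours by construction, to 5 of 30 for cadherins (p = 0.00352), 5 of 14 for Cntnap (p = 0.0635) and 2 of 9 for contactin genes (p = 0.0406, Fisher's exact test, unadjusted), and leaves the protocadherin and Slitrk neighbours as they were. Major urinary protein genes, a tandem family, had 14 of 22 (adjusted p = 1.74e-05), and 5 of 6 Obox genes were listed (adjusted p = 0.0132, Fisher's exact test). The genes beside them were listed in 0 of 4 and 0 of 2 cases (unadjusted p = 0.0331 and 0.107, adjusted p = 0.132 and 0.286, Fisher's exact test). The urinary protein genes were listed at 10 peaks. Genes that share a peak are not independent, so p-values of such families may be too small. Olfactory receptor genes were listed less often than other genes, 85 of 1110 (7.66%, adjusted p = 4.14e-05, Fisher's exact test), while the genes beside them had 13 of 174 (7.47%), or 5 of 174 (2.87%) without peaks shared with an olfactory receptor gene. The 85 genes were listed at 54 peaks, so this test also counts genes that share a peak.

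Peaks were unevenly spread over the chromosomes. Chromosome X held 234 peaks, or 24.2 per 100 protein-coding genes, chromosome 11 held 79 (4.91) and chromosome 19 held 30 (4.26). Chromosome 8 had the highest density at 1.49 peaks per Mb, and chromosome 19 the lowest at 0.490, apart from Y with 1 peak. The correlation of peaks per Mb with genes per Mb across 20 chromosomes was negative, and not every version passed 0.05 (Pearson r −0.476, permutation p = 0.0346, Spearman rho −0.418, permutation p = 0.0684), with Mb counted up to the last peak. Without chromosomes 11 and 7, the 2 farthest in gene density, r was −0.505 (permutation p = 0.0327, rho −0.426, permutation p = 0.0796), and over the 19 autosomes it was −0.427 (permutation p = 0.0696, rho −0.374, permutation p = 0.114). With peaks outside clusters, r over the 20 chromosomes was −0.584 (permutation p = 0.00733) and rho −0.532 (permutation p = 0.0174). These are versions of 1 relation, and their p-values were not adjusted. A single line lists 3 genes, Shh and Rnf32 at 412 and 317 kb and Evc2 at 8525 kb.

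Fold values stood on a few levels, and scores just above the lowest one listed. Of the 2741 peaks, 1434 (52.3%) had a fold that was a whole multiple of 3.6847 to within 0.0065, and 1370 of these stood at 4, 5 or 6 units. Under a Poisson model in which 1 unit is 1 read over the background of an extended read, an extension length of 53 bp gave a whole number of reads for 99.9% of their scores to within 0.1. The next best length, 39 bp, gave 15.3%. The median was then 7 reads per peak, with a range of 6 to 15, so these peaks may rest on few reads, and the 53 bp is consistent with an extension far below the 500 bp fragments. The other peaks were not fitted, and no biological explanation was tested.

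The strongest scores stood at low fold and often in clusters. Uniform chance placement is argued against by the 56 peaks between Ezh2 and Pdia4, since 1000 uniform placements never gave more than 8 in a cluster. Of the 43 peaks with a score of at least 150, 21 (48.8%) lay in clusters, against 7.19% of the other peaks (p = 5.33e-13, Fisher's exact test). Peaks of the same cluster share a locus and are not independent, so this p may be too small. Repeated or extra-copy sequence that raises the input as well is a candidate explanation, but the difference in median fold of −10.63 between the 43 and the others (permutation p = 0.0001, the smallest the permutations can give) restates the pattern and does not single it out. Sequence content was not analysed here, so it stays open, and no biological explanation was tested.

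Enteric neural crest genes were listed at peaks more often than other genes, a call that ended with the upper part of peaks by score and with the nearest gene only (adjusted p = 0.101 and 0.374, Fisher's exact test). Peaks in clusters are argued against as the cause, since none of the listed crest genes had its strongest peak in a cluster. Leaving out the clustered peaks therefore could not remove a gene, and the list still had 9 listed (unadjusted p = 0.00219, Fisher's exact test). Repeated sequence outside clusters was not tested by this and stays open. Wide spacing of genes around these loci stays open. Within 50 kb of the gene, a limit added after the data were seen, 1 of the 25 list genes was listed, where 1.12 would be expected (ratio 0.897). The excess therefore lay at peaks farther away, as wide spacing would give, but so few expected genes cannot decide it. Of the 49 genes next to the list's genes, 16 were listed (32.7%, p = 0.799 against the list, Fisher's exact test), but 7 of them only at a peak that also lists a gene of the list. The other 9 (18.4%, exact interval 8.76 to 32.02) lie between the 12.5% of all protein-coding genes and the 36.0% of the list, and did not decide it (p = 0.151 against the list, Fisher's exact test). The design holds no sample that separates neural crest cells from other cells, so no biological explanation was tested.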
